A study of Homo sapiens with 12 samples.

How the data were processed

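Total RNA from the immortalised human bronchial epithelial cell line 16HBE was labelled with biotin as cRNA and hybridised to Illumina bead arrays, per the labels' protocols, with 1 array per sample. The 12 samples formed 4 groups of 3, and the design text names 3 independent experiments that each gave 1 sample of every group. The titles number the samples 1 to 3 within each group, and these numbers name the replicates here. Groups were taken from the labels alone.

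The deposited table holds the mean bead intensity of 47322 probes on each array, not normalized, with the number of beads, the bead standard error and a detection p-value. Each deposited detection p-value ranks a probe against the negative controls of its array and moves in steps of 1 part in 770. GenomeStudio is named in the submitters' processing notes, and its version, scanner settings and further steps are not given in the sources used here. A deposited series table holds the authors' processed intensity values of 47317 of the same probes; these values go below 0 and share their quantiles between arrays, and they served as an alternative. No background subtraction was evident in the first table, whose lowest values lie well above 0. No column belonged to a sample outside the series.

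Intensities were corrected for background and normalized between arrays with limma's neqc, which estimates the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Quantile normalization gives every array the same distribution, so a change of most genes in one direction would be removed. The platform annotation given with the series names 30112 probes with 1 gene symbol, 8 with several and 17202 with none. Probes with several symbols were left unnamed. A probe was kept if its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 17099 probes, 13885 of them named. For 2760 genes with several kept probes, the probe with the highest mean over all arrays stood for the gene. Among the genes of the text with further kept probes, none had another probe called in the opposite direction in a comparison with control. Comparisons between inhibited groups were not checked in this way. This gave 10532 genes. The 3214 kept probes without a symbol were tested separately. The annotation can be old, and no genome coordinates were used here.

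The tests were limma's lmFit and eBayes over the 4 group means, with all 12 arrays sharing 1 estimate of the spread, and Benjamini-Hochberg adjustment across genes with a threshold of 0.05. The median SD of a gene after limma's moderation was 0.169 on the log2 scale. Each inhibited group was compared with control, as the design text does, and the inhibited groups were compared with each other. A moderated F-test asked whether a gene differed among the 4 groups. Samples of a group came from separate experiments, per the design text, so the p-values measure the spread between experiments on a single cell line.

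46 lists of genes were fixed by pathway, process and cell type, and 42 of them had at least 5 measured genes. These were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data. Members that passed were counted over all genes and with adjustment over the list alone. The score list holds transcripts known to report the activity of the MEK/ERK pathway. Where a gene was detected on no array of a group, its change is printed as a lower bound: the mean of the brighter group against, for each array of the dimmer group, the higher of the gene's own value and the lowest detected value of that array. List medians were computed again with such genes at their bounds.

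The genes in the text were named by a rule. For each comparison with control it took the 8 largest rises and the 8 largest falls among genes that passed limma's test with the same sign in all 3 same-numbered differences, the score genes, the measured Ras gene, and up to 4 members with the smallest adjusted p of each list past the threshold. For comparisons between inhibited groups it took the 5 largest rises and falls and the same list members, and for genes changed alike in all 3 groups the 8 largest rises and falls by the smallest of the 3 changes. Symbols starting with LOC, HS. or FLJ were left out. Genes outside this rule are said to have been chosen after their values were seen. The groups, tests, gene lists, naming rule and alternatives were set before the data were examined.

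The fit was tested on normal noise simulated from these genes' means and limma's variances, with 10532 genes, 200 of them changed per run, in 5 runs for each comparison. For the MEK inhibitor against control it recovered 38.2% of genes changed by 0.5 on the log2 scale, 99.4% of those changed by 1 and 100% of those changed by 2, and 5.83% of its calls were false. For the ERK inhibitor against control these values were 38.2%, 97.6% and 100%, with 5.65% false calls. For dominant-negative Ras against control they were 39.7%, 98.8% and 100%, with 3.41% false calls. For the MEK against the ERK inhibitor they were 40.3%, 97.9% and 100%, with 4.57% false calls. For dominant-negative Ras against the MEK inhibitor they were 38.5%, 98.5% and 100%, with 4.13% false calls. For dominant-negative Ras against the ERK inhibitor they were 37.9%, 97.9% and 100%, with 4.50% false calls. The simulated genes were uncorrelated, no simulated array stood apart, and fewer genes changed than were called in the real data. These rates therefore hold under the model's own assumptions.

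The comparisons with control share the control arrays, so overlap between them was also computed for simulated groups without any effect, in 50 simulations. Alternatives changed 1 choice at a time: the background correction and its offset (50 in place of 16), the normalization, the authors' processed values, the probe filter, the probe chosen for a gene, the samples in the fit, the variance model, array weights, the experiment number, the thresholds and each array in turn. The analysis used R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9 for the plots.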

Results

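The human bronchial epithelial cell line 16HBE, an immortalised line from the airway lining, was profiled on 12 Illumina bead arrays in 4 groups of 3. Control cells carried an empty retroviral vector and received the solvent DMSO for 4 days. Vector cells in 2 further groups received GSK1120212, a MEK inhibitor, at 500 nM, or SCH772984, an ERK inhibitor, at 1 µM for the same 4 days. The fourth group carried a vector for dominant-negative Ras, a form that blocks activation of normal Ras, and its labels give neither a solvent nor a treatment time. Ras, MEK and ERK act in this order in a kinase cascade, and the series asked how expression changed against control when the cascade was inhibited at each level.

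Of 47322 probes, 16825 to 18295 were detected on each array, with a median of 21 or 22 beads behind each probe value. Across genes, arrays of a group correlated at r = 0.978 to 0.993, a relation between genes, which are not independent replicates. Dominant-negative Ras replicate 3 stood apart, with 85 genes at least 2-fold beyond both other arrays of its group, against 22 or fewer on any other array. Few markers of other cell types were detected. Of 15 leukocyte genes on the array, 4 were detected on all 3 arrays in every group, while PTPRC, the common leukocyte antigen, and CD3D, a T cell receptor subunit, were not. The counts for 12 fibroblast genes were 3, 4, 3 and 3 in control, MEK inhibitor, ERK inhibitor and dominant-negative Ras cells, and for 12 endothelial genes 1, 2, 3 and 1. Of 6 EGFR ligand genes on the array, 3, 4, 3 and 3 were detected. Each of these lists had too few measured genes for a test. Of 4 measured fibroblast genes, 3, 2 and 2 were higher with the MEK inhibitor, the ERK inhibitor and dominant-negative Ras (1 in the last under median scaling) and 0 lower.

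Changes below are log2 differences ± SE from limma with 3 arrays per group, for 10532 genes, and the number of arrays limits their precision. A gene detected on no array of a group has a lower bound in its place ("at least" so many fold), beside the adjusted p of the fit. Scaling the arrays to 1 median in place of quantiles left the median change of all genes at −0.12 with the MEK inhibitor, at 0.12 with the ERK inhibitor and at −0.10 with dominant-negative Ras, each against control. Between groups that median was −0.24 for the MEK against the ERK inhibitor, 0.02 for dominant-negative Ras against the MEK inhibitor and −0.23 against the ERK inhibitor. The balance of higher and lower calls moved with it. List medians under median scaling are given relative to these medians, or with them beside. The scaling used the median of all 47322 probes, of which 35.6% to 38.7% were detected on an array. It thus aligned the arrays on a value near background, so these shifts do not measure a general change of expression.

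**Figure D1:**
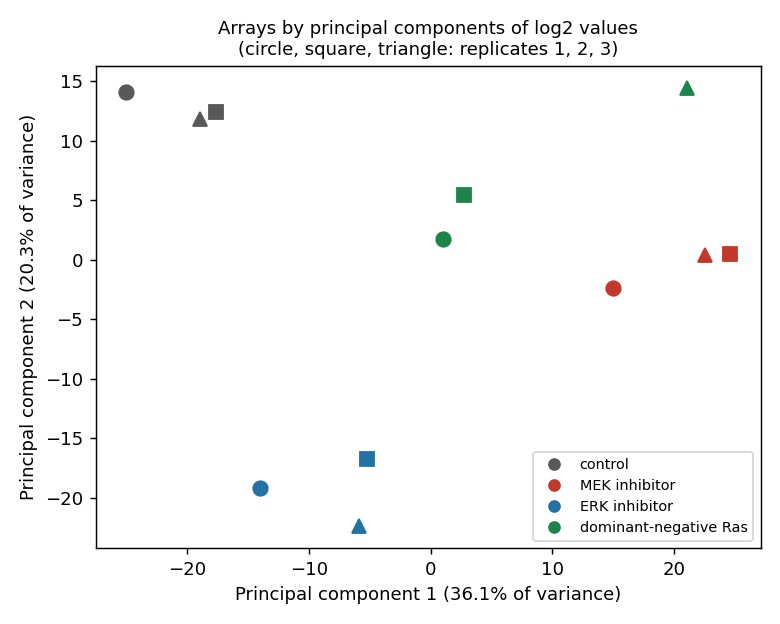
Each point is 1 array placed on principal components 1 (36.1% of variance) and 2 (20.3%) of log2 values, colored by group, with circle, square and triangle for replicates 1, 2 and 3. Arrays lay together by group except dominant-negative Ras replicate 3, at 21.1 on component 1 against 0.980 and 2.69 for replicates 1 and 2 and level with the MEK inhibitor arrays (15.0 to 24.6) on that component alone. On component 2 it lay at 14.4, against −2.42 to 0.47 for the MEK inhibitor and 11.8 to 14.1 for control.

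With MEK inhibited, EGR1, FOSL1 and TGM2 fell. EGR1, an immediate-early transcription factor, went from a mean log2 intensity of 8.47 ± 0.26 to 5.27 ± 0.15 (SD, n = 3 each), a change of −3.20 ± 0.16 (limma adjusted p = 2.43e-09). FOSL1, an AP-1 subunit, fell at least 9.10-fold (limma adjusted p = 9.26e-09). TGM2, which encodes tissue transglutaminase, had the largest fall, −6.13 ± 0.20 to a level detected on 1 of 3 arrays (limma adjusted p = 2.95e-11). The largest rises were in ACKR3, a scavenging chemokine receptor (4.25 ± 0.51), and MFAP5, a microfibril protein (4.24 ± 0.29). The chemokine gene CXCL8, the cholesterol synthesis gene DHCR7 and the sodium channel gene SCNN1A fell as well.

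Other large rises with the MEK inhibitor were in the small GTPase RHOB (2.58 ± 0.14), the thioredoxin-binding TXNIP (2.77 ± 0.25), C5orf46 (2.94 ± 0.20, detected on 1 of 3 control arrays) and GASK1B (2.55 ± 0.33, on 2 of 3 control arrays). IGFBP5, a binding protein of insulin-like growth factors, and NPPB, the precursor of B-type natriuretic peptide, were detected on no control array. They rose at least 11.5-fold (limma adjusted p = 0.00415) and at least 6.61-fold (8.56e-05). Among the falls, MYEOV and the steroid enzyme gene HSD3B1 were not detected with the inhibitor and fell at least 16.7-fold (limma adjusted p = 5.72e-09) and at least 6.08-fold (2.2e-10). FGFBP1, which carries fibroblast growth factors, changed by −3.54 ± 0.27. CCND2, a D-type cyclin, changed by −3.63 ± 0.32 and was detected on 1 of 3 inhibitor arrays. HRAS, the Ras gene measured here, did not pass (0.36 ± 0.13, limma adjusted p = 0.0773), and other Ras genes were not analysed here.

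Of the 9 measured score genes, transcripts that report MEK/ERK activity, 8 fell with the MEK inhibitor and 0 rose; adjusted over the list alone, 8 fell and EPHA4 rose. Their median change was −1.88, also with 5 members at their bounds (limma's camera adjusted p = 8.08e-14; adjusted p = 0.0071 with an estimated correlation). PHLDA1 changed by −2.95 ± 0.14, the receptor tyrosine kinase EPHA2 by −2.12 ± 0.12, the D cyclin CCND1 by −2.06 ± 0.17 and the feedback inhibitor SPRY2 by −1.88 ± 0.13. The ERK phosphatase DUSP6, the ETS factors ETV4 and ETV5 and the feedback inhibitor SPRY4 were not detected with the inhibitor. They fell at least 2.38-fold, 2.78-fold, 4.63-fold and 2.03-fold, with limma adjusted p-values of 8.88e-07, 8.88e-07, 2.48e-08 and 1.26e-06. EPHA4, detected on no control array, was at least 1.21-fold higher and did not pass over all genes (limma adjusted p = 0.0898). In a wider list of 26 ERK feedback and immediate-early genes, 10 fell and 2 rose (adjusted over the list alone, 11 and 4). Its median was −0.22, or −0.18 with members at their bounds (limma's camera adjusted p = 0.000141; adjusted p = 0.183 with an estimated correlation). SPRED1, a feedback inhibitor, changed by −2.92 ± 0.16 and the phosphatase gene DUSP5 by −2.31 ± 0.14.

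Inflammatory genes were lower with the MEK inhibitor: 8 of 20 NF-kB and cytokine genes fell and 0 rose (adjusted over the list alone, 10 and 0). The list's median was −0.44 (limma's camera adjusted p = 8.08e-06; adjusted p = 0.271 with an estimated correlation). The neutrophil chemokines CXCL8 and CXCL1 changed by −3.25 ± 0.22 and −2.49 ± 0.36, interleukin gene IL1A by −2.15 ± 0.19, and its natural antagonist IL1RN fell at least 2.96-fold (limma adjusted p = 6.62e-06). Interferon response genes had a median of −0.23, with 6 of 34 lower and 2 higher (adjusted over the list alone, 7 and 2; limma's camera adjusted p = 0.0139; adjusted p = 0.529 with an estimated correlation). With members at their bounds that median was −0.22, and without MEK inhibitor replicate 3 the list's adjusted p was 0.157. OAS1, an antiviral enzyme gene, changed by −0.73 ± 0.14, and EPSTI1 rose by 0.60 ± 0.13, a call lost under median scaling (limma adjusted p = 0.143).

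Among 8 ion channel and airway transport genes, 7 fell and 0 rose with the MEK inhibitor (adjusted over the list alone, 7 and 1), with a median of −0.61 (limma's camera adjusted p = 5.1e-05; adjusted p = 0.0311 with an estimated correlation). SCNN1A, a subunit of the epithelial sodium channel, changed by −2.09 ± 0.17 and ANO1, a calcium-activated chloride channel, by −1.13 ± 0.13. Squamous differentiation genes split, with 9 of 20 lower and 2 higher, both in the all-gene count and adjusted over the list alone, and a median of −0.38. That list's camera adjusted p in limma was 0.00542 (adjusted p = 0.471 with an estimated correlation), and it was 0.0602 over probes detected on all 12 arrays. S100A9, a calprotectin subunit, changed by −2.12 ± 0.24, while TGM1, a keratinocyte transglutaminase, and the keratin KRT16 rose by 1.00 ± 0.14 and 1.43 ± 0.20.

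Cholesterol synthesis genes were lower. Of 20 cholesterol synthesis genes, 11 fell and 0 rose (adjusted over the list alone, 11 and 0), with a median of −0.49 (limma's camera adjusted p = 8.08e-06; adjusted p = 0.271 with an estimated correlation). DHCR7, which makes cholesterol in the last step of one branch, changed by −1.03 ± 0.17, INSIG1 by −0.73 ± 0.14 and NSDHL by −0.65 ± 0.10. For 14 fatty acid synthesis genes the median was −0.37, with 5 lower and 0 higher (adjusted over the list alone, 7 and 1; limma's camera adjusted p = 0.0139; adjusted p = 0.453 with an estimated correlation). Without MEK inhibitor replicate 3 that list's adjusted p was 0.0522. The fatty acid elongase ELOVL6 changed by −0.95 ± 0.13 and the synthase FASN by −0.72 ± 0.15. Glycolysis genes had a median of −0.17, with 5 of 20 lower and 0 higher (adjusted over the list alone, 7 and 1; limma's camera adjusted p = 0.0137; adjusted p = 0.271 with an estimated correlation). Among them were GPI (−0.76 ± 0.13), PFKL (−0.64 ± 0.12) and the glucose transporter SLC2A1 (−0.54 ± 0.12).

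Ribosome biogenesis genes had a median of −0.24 with the MEK inhibitor, with 7 of 27 lower and 0 higher (adjusted over the list alone, 10 and 0; limma's camera adjusted p = 0.00096; adjusted p = 0.183 with an estimated correlation). NOP2, an rRNA methyltransferase, changed by −0.60 ± 0.11. Of 31 cytoskeleton and migration genes, 9 rose and 2 fell (adjusted over the list alone, 12 and 2), with a median of 0.13. Median scaling turned that median to −0.02, or 0.10 relative to all genes (limma's camera adjusted p = 0.0113; adjusted p = 0.183 with an estimated correlation). The actin-linking RDX and the bundling protein FSCN1 rose by 0.77 ± 0.11 and 0.72 ± 0.11, and the GTPase RAC2 changed by −1.09 ± 0.15. Among 36 genes of the G2/M phase, 5 rose and 0 fell (adjusted over the list alone, 5 and 0), with a median of 0.12 that turned to −0.03 under median scaling, or 0.09 relative to all genes. That list's camera adjusted p in limma was 0.00542 (adjusted p = 0.457 with an estimated correlation), and CENPA, a centromere histone, was among the rises (0.46 ± 0.11), though not under median scaling (adjusted p = 0.358). The list of G1 cyclins and CDKs lay at the threshold (limma's camera adjusted p = 0.05; adjusted p = 0.323 with an estimated correlation), with a median of −0.28, 4 of 11 lower and 1 higher (adjusted over the list alone, 4 and 1). Without control replicate 1, MEK inhibitor replicate 3, ERK inhibitor replicate 2 or 3 or dominant-negative Ras replicate 1 its adjusted p was 0.0718, 0.0655, 0.0553, 0.0562 and 0.0575. It was 0.0516 with the authors' processed values, 0.229 over probes detected on all 12 arrays and 0.0655 with the mean of all probes of a gene.

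In all, limma called 1682 genes changed with the MEK inhibitor, 749 higher and 933 lower, and 329 of them changed at least 2-fold. Higher genes made up 44.5% of the calls, and 22.4% under median scaling. Without control replicate 1 or MEK inhibitor replicate 2 the count was 1035 and 1059. It was 2023 without dominant-negative Ras replicate 3, which is outside this comparison but enters the shared estimate of the spread. Camera called 13 of 42 lists, and 2 with an estimated correlation, the score and ion channel lists.

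**Figure D2:**
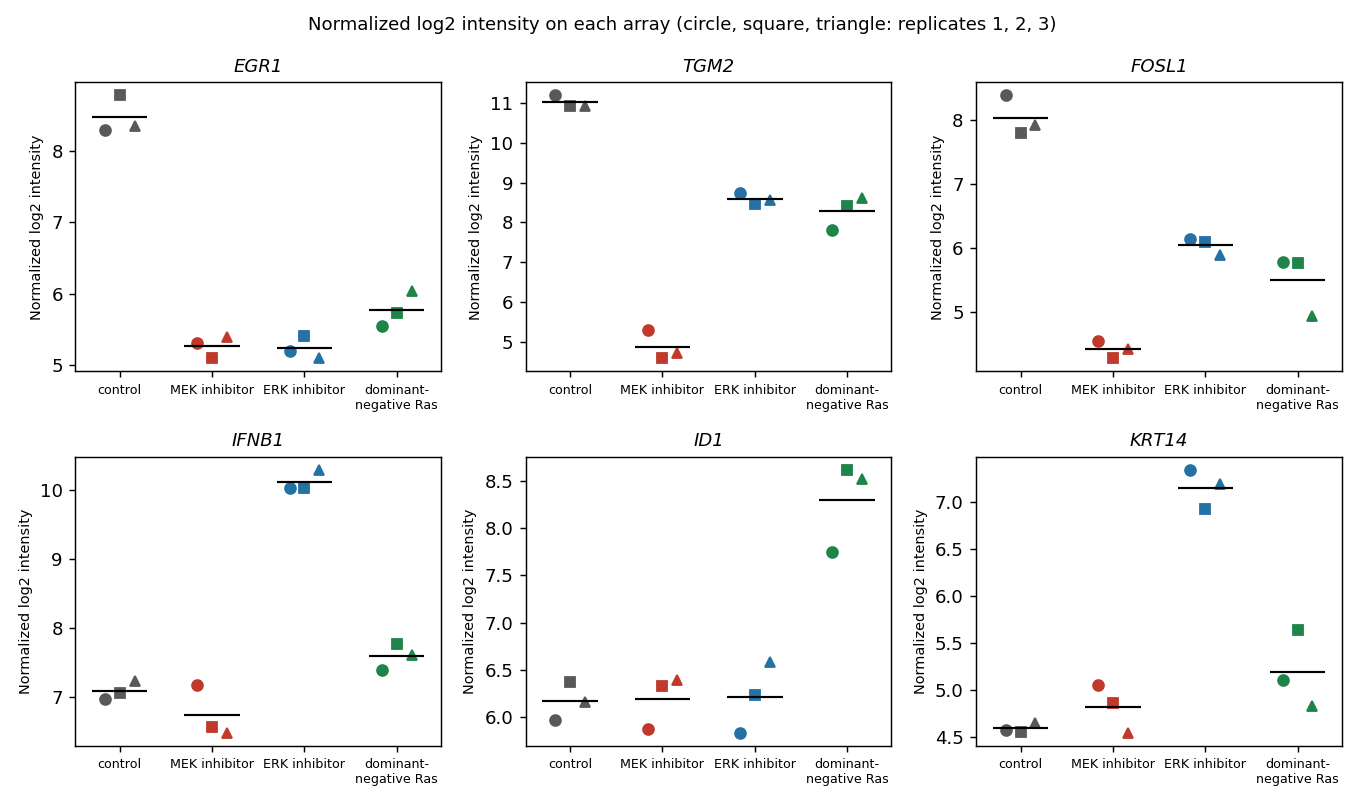
Normalized log2 intensity of EGR1, TGM2, FOSL1, IFNB1, ID1 and KRT14 on each of the 12 arrays by group, with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. EGR1 was below its control values (mean 8.47) on every inhibited array, whereas IFNB1 stood above all other arrays with the ERK inhibitor only (mean 10.12) and ID1 with dominant-negative Ras only (mean 8.30).

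With ERK inhibited, the pathway outputs EGR1 and FOSL1 fell, and the interferon gene IFNB1 rose. EGR1 changed by −3.24 ± 0.16 (limma adjusted p = 5.24e-09) and FOSL1 by −2.00 ± 0.20 (1.02e-05). IFNB1, which encodes interferon beta, went from a mean log2 intensity of 7.09 ± 0.13 to 10.12 ± 0.15 (SD, n = 3 each), a rise of 3.03 ± 0.17 (limma adjusted p = 2.55e-08). The interferon-induced chemokine CXCL10 rose by 2.79 ± 0.24 and the interferon lambda gene IFNL1 by 2.37 ± 0.18, whose probe could also read its near copies IFNL2 and IFNL3. Keratins KRT14, a marker of basal cells, and KRT16 rose as well, at least 4.93-fold (limma adjusted p = 4.23e-07) and by 2.65 ± 0.20. The list of basal airway genes, KRT14 among them, had a median of −0.01 with the ERK inhibitor and did not pass.

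NPPB and the skeletal muscle actin gene ACTA1 were detected on no control array and rose at least 7.28-fold (limma adjusted p = 9.07e-05) and at least 5.11-fold (2.28e-09) with the ERK inhibitor. C5orf46 rose by 3.15 ± 0.20 from a level detected on 1 of 3 control arrays. TGM2 changed by −2.42 ± 0.20, HSD3B1 by −2.17 ± 0.12, the calcium-binding CALB2 by −1.96 ± 0.30 and MIA by −1.90 ± 0.18. HRAS did not pass (0.20 ± 0.13, limma adjusted p = 0.36).

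Interferon response genes rose as a group with the ERK inhibitor: 23 of 34 were higher and 0 lower (adjusted over the list alone, 26 and 0), with a median of 0.70. The call rested on the preset correlation (limma's camera adjusted p = 4.11e-19; adjusted p = 0.0588 with an estimated correlation). The antiviral genes OAS2, OASL and RSAD2 rose by 1.65 ± 0.15, 1.94 ± 0.22 and 2.07 ± 0.21, and IFIH1, a sensor of double-stranded RNA, by 1.31 ± 0.13. Of the 17 genes for MHC and antigen presentation, 9 rose and 0 fell (adjusted over the list alone, 10 and 0), with a median of 0.48 (limma's camera adjusted p = 0.000216; adjusted p = 0.263 with an estimated correlation). The peptide transporter TAP1 rose by 0.71 ± 0.13, and HLA-F and HLA-G, whose probes may read related HLA genes, by 0.95 ± 0.16 and 0.86 ± 0.15. Leukocyte genes detected on all 3 arrays numbered 4 here and 4 in control.

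Score genes had a median of −1.37 with the ERK inhibitor, and −1.08 with members at their bounds, with 6 of 9 lower and 0 higher (adjusted over the list alone, 7 and 1). The list passed with the preset correlation (limma's camera adjusted p = 1.27e-07; adjusted p = 0.0549 with an estimated correlation). PHLDA1 changed by −1.48 ± 0.14, ETV5 by −1.64 ± 0.18, and ETV4 (−1.59 ± 0.15) and DUSP6 (−1.37 ± 0.15) were each detected on 1 of 3 inhibitor arrays. SPRY4 was not detected and fell at least 2.12-fold (limma adjusted p = 8.79e-06). EPHA2 lay near the threshold (−0.42 ± 0.12, limma adjusted p = 0.0372). Its adjusted p was 0.118, 0.0719 and 0.0928 without control replicates 1, 2 and 3, and 0.0598, 0.0731 and 0.125 without ERK inhibitor replicates 1, 2 and 3. CCND1 (−0.49 ± 0.17), SPRY2 (−0.23 ± 0.13) and EPHA4 (at least 1.18-fold higher) did not pass (limma adjusted p = 0.0801, 0.278 and 0.126). CCND1 passed without dominant-negative Ras replicate 3 (limma adjusted p = 0.0232), as did EPHA4 (0.00477).

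**Figure D3:**
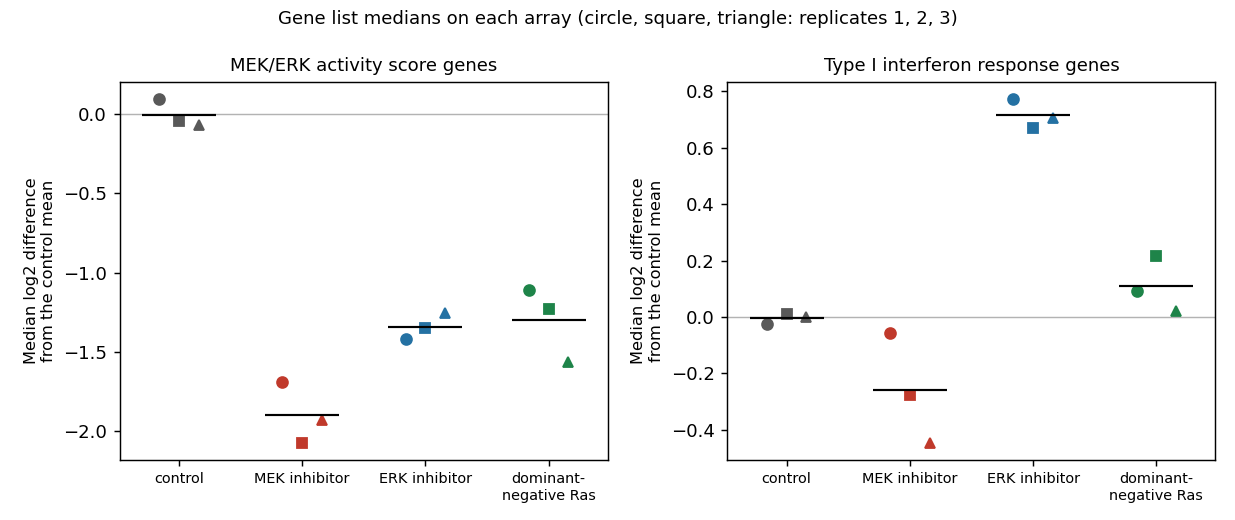
Median log2 difference from the control mean of the score genes (left) and the interferon response genes (right) on each of the 12 arrays, with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. Score medians were −2.07 to −1.69 with the MEK inhibitor, −1.42 to −1.26 with the ERK inhibitor and −1.57 to −1.11 with dominant-negative Ras, and the interferon medians of the ERK inhibitor arrays, 0.67 to 0.77, lay above all other arrays.

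With the ERK inhibitor, cholesterol synthesis genes had a median of −0.34, with 8 of 20 lower and 0 higher (adjusted over the list alone, 10 and 0; limma's camera adjusted p = 1.15e-05; adjusted p = 0.217 with an estimated correlation). DHCR7 changed by −0.82 ± 0.17. For fatty acid synthesis the median was −0.52, with 7 of 14 lower and 1 higher (adjusted over the list alone, 10 and 1; limma's camera adjusted p = 0.000237; adjusted p = 0.212 with an estimated correlation). FASN changed by −1.04 ± 0.15 and ELOVL6 by −0.94 ± 0.13. Ribosome biogenesis genes had a median of −0.26, with 5 of 27 lower and 0 higher (adjusted over the list alone, 7 and 0; limma's camera adjusted p = 5.69e-05; adjusted p = 0.0596 with an estimated correlation). HEATR1 changed by −0.60 ± 0.12. Of 29 cytosolic ribosomal protein genes, 4 fell and 0 rose (adjusted over the list alone, 6 and 0), with a median of −0.17 (limma's camera adjusted p = 0.00706; adjusted p = 0.0596 with an estimated correlation). RPL4, of the large subunit, changed by −0.59 ± 0.12, and neither RPL4 nor HEATR1 passed under median scaling (limma adjusted p = 0.101 and 0.182).

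Of 26 ATF4 and unfolded protein response genes, 8 rose and 0 fell with the ERK inhibitor (adjusted over the list alone, 10 and 1), with a median of 0.24 (limma's camera adjusted p = 0.000138; adjusted p = 0.278 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 1.60 ± 0.12 and XBP1, a regulator of the unfolded protein response, by 0.67 ± 0.12. Among 31 cytoskeleton and migration genes, 8 rose and 0 fell (adjusted over the list alone, 8 and 0), with a median of 0.21 (limma's camera adjusted p = 0.000647; adjusted p = 0.0596 with an estimated correlation). RHOB rose by 1.27 ± 0.14 and the myosin light chain gene MYL9 by 0.90 ± 0.17.

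The mesenchymal list had a median of 0.23 with the ERK inhibitor, with 6 of 17 higher and 1 lower (adjusted over the list alone, 7 and 1; limma's camera adjusted p = 0.0449; adjusted p = 0.212 with an estimated correlation). With members at their bounds that median was 0.00, and with no filter on detection it was −0.03 (adjusted p = 0.301). TAGLN and CALD1, actin-binding proteins of contractile cells, rose by 1.73 ± 0.17 and 1.17 ± 0.13, the collagen gene COL5A1 by 1.32 ± 0.14 and the N-cadherin gene CDH2 by 1.19 ± 0.24. In the TGF-beta and BMP list 4 of 15 rose and 1 fell (adjusted over the list alone, 4 and 1), with a median of 0.27 (limma's camera adjusted p = 0.0449; adjusted p = 0.212 with an estimated correlation). BAMBI, a decoy TGF-beta receptor, rose by 1.73 ± 0.12, and ID3 and ID4, inhibitors of basic helix-loop-helix factors, by 1.29 ± 0.12 and 1.34 ± 0.20. Both list calls were lost without control replicate 3 (adjusted p = 0.0642 for each). For the mesenchymal list the same held without MEK inhibitor replicate 1 (0.0525), ERK inhibitor replicate 1 (0.087) and dominant-negative Ras replicates 1 (0.0685) and 2 (0.0534). It also held with cyclic loess (0.0713), with array weights (0.0679) and with only the 2 groups compared (0.0745). For the TGF-beta list it held without MEK inhibitor replicate 1 (0.0525), ERK inhibitor replicate 3 (0.0648) and dominant-negative Ras replicate 2 (0.0506), with no background correction (0.0822) and with the mean of all probes of a gene (0.0643).

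In all, limma called 1201 genes with the ERK inhibitor, 624 higher and 577 lower, and 190 changed at least 2-fold. Higher genes made up 52.0% of the calls, and 84.3% of 747 calls under median scaling. Without control replicate 1, 2 or 3 the count was 634, 745 and 699, and without ERK inhibitor replicate 2 or 3 it was 725 and 706. It was 1547 without dominant-negative Ras replicate 3, which enters only the shared estimate of the spread. Camera called 11 lists, and 0 with an estimated correlation.

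With dominant-negative Ras, the pathway outputs EGR1 and FOSL1 fell, and the transcription regulators KLF2 and ID1 to ID4 rose. EGR1 changed by −2.70 ± 0.16 (limma adjusted p = 3.88e-08), FOSL1 by −2.54 ± 0.20 (1.11e-06) and TGM2 by −2.72 ± 0.20 (6.09e-07). KLF2, a Krüppel-like transcription factor, went from a mean log2 intensity of 7.12 ± 0.15 to 10.02 ± 0.13 (SD, n = 3 each), a rise of 2.90 ± 0.16 (limma adjusted p = 1.99e-08). Of the inhibitors of basic helix-loop-helix factors, ID1 rose by 2.14 ± 0.23, ID3 by 1.85 ± 0.12, ID4 by 1.71 ± 0.20, and ID2 by 2.75 ± 0.35 from a level detected on 1 of 3 control arrays. MVD and FDPS, of cholesterol synthesis, fell.

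RHOB rose by 2.63 ± 0.14, TXNIP by 2.37 ± 0.25, C5orf46 by 2.19 ± 0.20 and ACKR3 by 2.80 ± 0.51 with dominant-negative Ras. Without replicate 3 of that group ACKR3 rose by 1.94 (limma adjusted p = 0.000638). IGFBP5 was at least 7.23-fold higher (limma adjusted p = 0.0193) with an SD of 2.56 between its arrays. The bound was 2.60-fold without dominant-negative Ras replicate 3, 12.6-fold without replicate 1 and 11.6-fold without replicate 2. That call was lost without control replicate 1, 2 or 3 (limma adjusted p = 0.0617, 0.0575 and 0.0501). FGFBP1 changed by −2.84 ± 0.27, MYEOV by −2.48 ± 0.24 and HSD3B1 by −2.61 ± 0.12, the last detected on 2 of 3 arrays. GDF15, a stress-induced cytokine, changed by −2.51 ± 0.16 and was detected on 1 of 3 arrays, and MIA changed by −2.29 ± 0.18 and was detected on 2 of 3. HRAS did not pass (0.26 ± 0.13, limma adjusted p = 0.226). Whether its probe reads the introduced Ras is not given in the sources used here, so it does not check the label.

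All score genes but EPHA4 fell, 8 of 9 (adjusted over the list alone, 8 lower and 0 higher), with a median of −1.25, or −1.20 with members at their bounds. The list held with either correlation (limma's camera adjusted p = 6.85e-12; adjusted p = 0.0118 with an estimated correlation). PHLDA1 changed by −1.67 ± 0.14, SPRY2 by −1.20 ± 0.13, CCND1 by −1.19 ± 0.17 and EPHA2 by −0.83 ± 0.12. ETV5 (−2.25 ± 0.18) and ETV4 (−1.74 ± 0.15) were each detected on 1 of 3 arrays and DUSP6 (−1.25 ± 0.15) on 2 of 3. SPRY4 was not detected and fell at least 2.13-fold (limma adjusted p = 1.12e-05). EPHA4 was at least 1.08-fold higher (limma adjusted p = 0.229). Of 26 feedback and immediate-early genes, 11 fell and 4 rose (adjusted over the list alone, 12 and 4), with a median of −0.18 (limma's camera adjusted p = 0.0107; adjusted p = 0.337 with an estimated correlation). Over probes detected on all 12 arrays that list did not pass (adjusted p = 0.139). DUSP5 and SPRED1 each changed by −1.65, with SE of 0.14 and 0.16.

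Cholesterol synthesis genes had a median of −0.51 with dominant-negative Ras, with 12 of 20 lower and 0 higher (adjusted over the list alone, 13 and 0; limma's camera adjusted p = 1.48e-09; adjusted p = 0.141 with an estimated correlation). MVD changed by −1.19 ± 0.17, the farnesyl diphosphate synthase FDPS by −1.02 ± 0.16 and NSDHL by −0.79 ± 0.10. Fatty acid synthesis genes had a median of −0.44, with 7 of 14 lower and 1 higher (adjusted over the list alone, 8 and 1; limma's camera adjusted p = 0.00162; adjusted p = 0.32 with an estimated correlation). ELOVL6 changed by −1.24 ± 0.13 and the desaturase SCD by −1.46 ± 0.27. Ribosome biogenesis genes had a median of −0.21, with 7 of 27 lower and 0 higher (adjusted over the list alone, 10 and 0; limma's camera adjusted p = 0.00162; adjusted p = 0.141 with an estimated correlation). BOP1 changed by −0.74 ± 0.14 and NOP2 by −0.60 ± 0.11.

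TGF-beta and BMP response genes rose with dominant-negative Ras: 6 of 15 were higher and 1 lower (adjusted over the list alone, 7 and 1), with a median of 0.36 (limma's camera adjusted p = 0.000206; adjusted p = 0.0799 with an estimated correlation). Besides the ID genes, BAMBI rose by 1.84 ± 0.12. Squamous genes fell on balance, 7 of 20 lower and 2 higher (adjusted over the list alone, 8 and 2), with a median of −0.41, or −0.37 with members at their bounds (limma's camera adjusted p = 0.00162; adjusted p = 0.413 with an estimated correlation). The kallikrein proteases KLK6 and KLK7 changed by −1.40 ± 0.17 and −2.19 ± 0.32, and TGM1 rose by 0.82 ± 0.14. Of 8 ion transport genes 2 fell and 1 rose (adjusted over the list alone, 3 and 1), with a median of −0.30 (limma's camera adjusted p = 0.0114; adjusted p = 0.141 with an estimated correlation). SCNN1A changed by −1.28 ± 0.17 and ANO1 by −1.07 ± 0.13. Of 13 genes for proteases of matrix turnover 5 fell and 1 rose (adjusted over the list alone, 5 and 2), with a median of −0.39 (limma's camera adjusted p = 0.0117; adjusted p = 0.477 with an estimated correlation). The plasminogen activators PLAT and PLAU changed by −1.37 ± 0.14 and −0.98 ± 0.14 and the protease inhibitor TIMP1 by −1.30 ± 0.18. With no filter on detection neither of the last 2 lists passed (adjusted p = 0.102 and 0.155), and the protease list's adjusted p was 0.0519 without control replicate 1 and 0.0877 over probes detected on all 12 arrays.

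In all, limma called 1291 genes with dominant-negative Ras, 612 higher and 679 lower, and 201 changed at least 2-fold. Higher genes made up 47.4% of the calls, and 23.1% of 718 calls under median scaling. Without control replicate 1 or 3 the count was 745 and 815, and without dominant-negative Ras replicate 3 it was 1020. Camera called 9 lists, and only the score list with an estimated correlation.

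**Figure D4:**
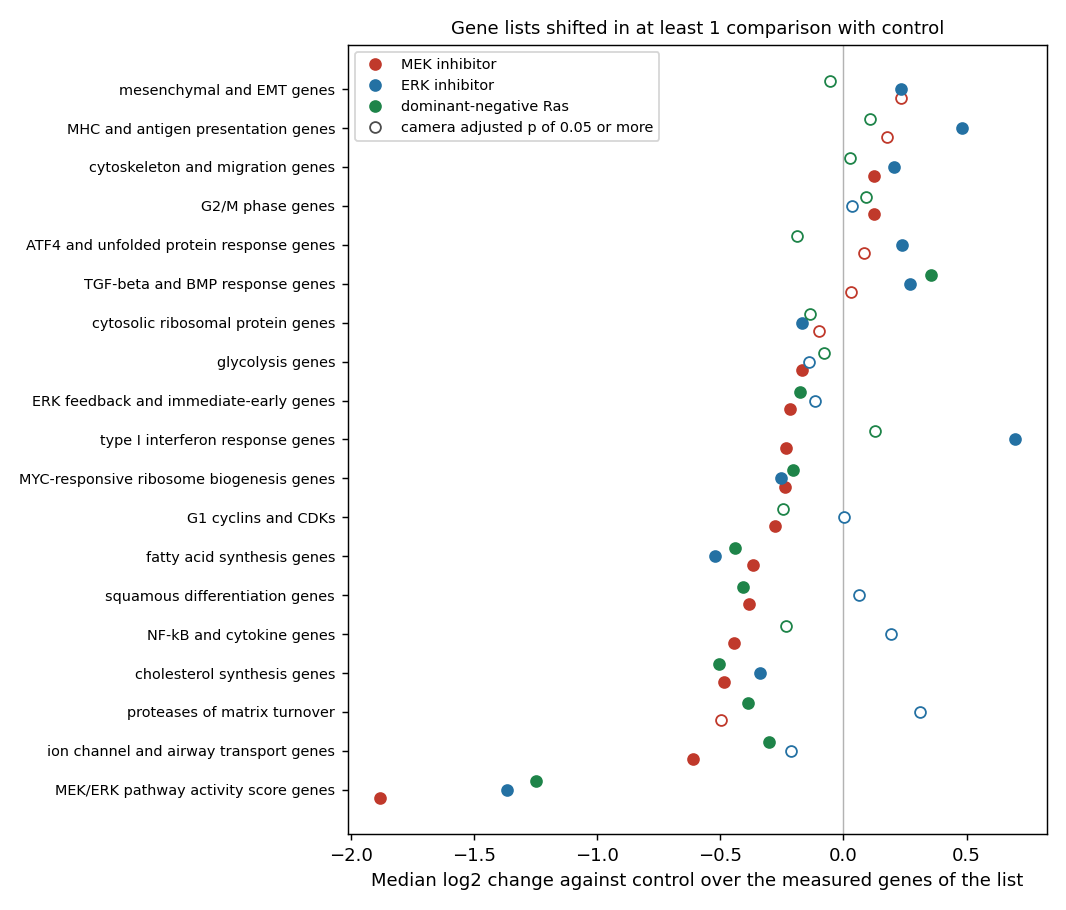
Median log2 change against control (horizontal axis) of each list that camera called in at least 1 comparison with control, with filled points for an adjusted p under 0.05 and open points otherwise, in red, blue and green for the MEK inhibitor, the ERK inhibitor and dominant-negative Ras. Score genes lay lowest (−1.88, −1.37 and −1.25) and interferon genes highest with the ERK inhibitor (0.70), while the G2/M and cytoskeleton medians with the MEK inhibitor turned to −0.03 and −0.02 under median scaling, or 0.09 and 0.10 relative to all genes.

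A common set of genes moved in all 3 inhibited groups. EGR1, FOSL1, TGM2, ETV4, ETV5, HSD3B1, MIA and FGFBP1 had the largest shared falls, and TXNIP, C5orf46, ACKR3, MFAP5, BAMBI, SYNC, C4BPB and ID4 the largest shared rises. MFAP5 rose by 4.24 ± 0.29, 1.79 ± 0.29 and 1.84 ± 0.29 with the MEK inhibitor, the ERK inhibitor and dominant-negative Ras. BAMBI rose by 2.04 ± 0.12, 1.73 ± 0.12 and 1.84 ± 0.12 in that order, and the complement regulator gene C4BPB by 1.64 ± 0.17, 1.37 ± 0.17 and 1.47 ± 0.17. SYNC, an intermediate filament protein gene, rose by 2.08 ± 0.22, 1.54 ± 0.22 and 1.42 ± 0.22. In total 348 genes changed the same way in all 3 groups, 148 higher and 200 lower, where independent lists of these sizes would share 2.58 and 3.30. Another 4 genes passed in all 3 groups without sharing a direction. The count was 152 under median scaling, 173 without control replicate 1, 229 without control replicate 3 and 224 without ERK inhibitor replicate 2. An F-test in limma called 2684 genes as differing among the 4 groups.

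Because the 3 comparisons share their control arrays, part of this overlap may come from those arrays, which were not split between the comparisons. Across genes, changes with the MEK inhibitor correlated with those of the ERK inhibitor at r = 0.572 and of dominant-negative Ras at r = 0.750, and the latter correlated with each other at r = 0.536. Simulated groups without effects gave r = 0.50, 0.499 and 0.497, and these are correlations between genes, which are not independent replicates. The covariances were 0.0844, 0.113 and 0.0652, against 0.0114, 0.0114 and 0.0113 in the simulations. The MEK and ERK inhibitor calls shared 591 genes, 255 higher and 312 lower in both (44.4 and 51.1 for independent lists), and 24 in opposite directions. MEK inhibitor and dominant-negative Ras calls shared 743 genes, 309 higher and 433 lower in both (43.5 and 60.2), and 1 in opposite directions. The ERK inhibitor and dominant-negative Ras shared 451, 197 higher and 245 lower in both (36.3 and 37.2), and 9 in opposite directions. In 50 simulations without effects 0 genes were called in both. Without effects hardly any gene can pass in a comparison, so this 0 does not bound what shared control noise adds beside real effects.

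The inhibitors were compared directly to see where blocking MEK differed from blocking ERK; they have different targets, and their doses (500 nM and 1 µM) differ. IFNB1 and the pathway genes EPHA2 and SPRY2 were lower with the MEK than with the ERK inhibitor, and so were the chemokine gene CXCL8 and the epithelial regulator KLF4. IFNB1 differed by −3.38 ± 0.17 (limma adjusted p = 1.46e-08), TGM2, on 1 of 3 MEK inhibitor arrays, by −3.71 ± 0.20 (1.46e-08) and LCN2, a secreted iron-binding protein, by −3.49 ± 0.52 (0.000416). MYEOV was at least 7.63-fold lower (limma adjusted p = 2.84e-07), and IFNL1, detected on 2 of 3 MEK inhibitor arrays, differed by −3.29 ± 0.18. MFAP5 was higher with the MEK inhibitor by 2.45 ± 0.29, ACKR3 by 2.36 ± 0.51, the copper transporter gene ATP7B by 2.20 ± 0.33 and the thyroid hormone deiodinase DIO2, detected on 2 of 3 ERK inhibitor arrays, by 2.21 ± 0.32.

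Of 34 interferon response genes, 25 were lower and 0 higher with the MEK than with the ERK inhibitor (adjusted over the list alone, 26 and 0), with a median of −0.87, or −0.82 with members at their bounds. The list held with either correlation (limma's camera adjusted p = 1.58e-25; adjusted p = 0.0246 with an estimated correlation). OAS2 differed by −2.27 ± 0.15 and the antiviral gene DDX60 by −1.88 ± 0.16. Score genes had a median of −1.22, or −0.57 with members at their bounds, with 5 of 9 lower and 0 higher (adjusted over the list alone, 6 and 0; limma's camera adjusted p = 3.44e-08; adjusted p = 0.0246 with an estimated correlation). EPHA2 differed by −1.70 ± 0.12, SPRY2 by −1.65 ± 0.13, CCND1 by −1.57 ± 0.17 and PHLDA1 by −1.47 ± 0.14, whereas EGR1, chosen after its values were seen, did not pass (0.03 ± 0.16, limma adjusted p = 0.934). EGR1 lay close to background with both inhibitors, which limits that comparison. NF-kB and cytokine genes had a median of −0.88, or −0.77 with members at their bounds, with 14 of 20 lower and 0 higher (adjusted over the list alone, 17 and 0; limma's camera adjusted p = 1.18e-16; adjusted p = 0.0514 with an estimated correlation). CXCL8 differed by −2.59 ± 0.22, TNF by −2.20 ± 0.31 and the NF-kB inhibitor TNFAIP3 by −1.70 ± 0.19. Squamous genes had a median of −0.59, with 10 of 20 lower and 0 higher (adjusted over the list alone, 13 and 1; limma's camera adjusted p = 6.27e-08; adjusted p = 0.146 with an estimated correlation). KLF4, a transcription factor of epithelial differentiation, differed by −1.81 ± 0.17 and the kallikrein KLK10 by −2.06 ± 0.23.

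With the MEK against the ERK inhibitor, 8 of 13 matrix protease genes were lower and 0 higher (adjusted over the list alone, 8 and 0), with a median of −0.72 (limma's camera adjusted p = 4.27e-05; adjusted p = 0.175 with an estimated correlation). MMP9 differed by −2.12 ± 0.29 and PLAU by −0.95 ± 0.14. Integrin and laminin genes had a median of −0.34, with 6 of 17 lower and 1 higher (adjusted over the list alone, 8 and 2; limma's camera adjusted p = 0.000162; adjusted p = 0.175 with an estimated correlation). The collagen receptor subunit ITGA2 differed by −1.91 ± 0.25 and ITGAV by −0.95 ± 0.14. KRT14, detected on 2 of 3 MEK inhibitor arrays, differed by −2.33 ± 0.18. In all, limma called 1076 genes, 371 higher with the MEK inhibitor and 705 lower, and camera 19 lists, of which 2 held with an estimated correlation. Higher genes made up 34.5% of the calls and 4.41% under median scaling. Without MEK inhibitor replicate 2 or 3 or ERK inhibitor replicate 1 the count was 575, 605 and 601. It was 1421 without dominant-negative Ras replicate 3, which enters only the shared estimate of the spread.

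Dominant-negative Ras was compared with the MEK inhibitor to see where blocking the top of the cascade differed from blocking its middle. The groups also differ in vector and compound, and the dominant-negative Ras labels give neither solvent nor treatment time. The level of the block cannot be told apart from these. TGM2 (3.41 ± 0.20, limma adjusted p = 1.03e-07), the chemokine CXCL8 (2.50 ± 0.22, 1.12e-05) and ID1 (2.11 ± 0.23, 0.00012) were higher with dominant-negative Ras. MYEOV was at least 3.00-fold higher (limma adjusted p = 0.000178). MFAP5 (−2.41 ± 0.29) and TNNC1, a troponin gene (−2.10 ± 0.26), were lower, and ACTA1, not detected with dominant-negative Ras, was at least 3.79-fold lower (limma adjusted p = 1.03e-07). NSG1 differed by −2.06 ± 0.21. Score genes were higher by a median of 0.61, or 0.00 with 4 members at their bounds, with 4 of 9 higher and 0 lower (adjusted over the list alone, 6 and 0; limma's camera adjusted p = 3.36e-06; adjusted p = 0.102 with an estimated correlation). EPHA2 differed by 1.29 ± 0.12 and PHLDA1 by 1.27 ± 0.14. Interferon genes had a median of 0.30 (0.28 at bounds), with 7 of 34 higher and 0 lower (adjusted over the list alone, 15 and 1; limma's camera adjusted p = 3.36e-06; adjusted p = 0.344 with an estimated correlation), and IFI27 differed by 1.78 ± 0.32. For NF-kB and cytokine genes the median was 0.36 (0.35 at bounds), with 4 of 20 higher and 0 lower (adjusted over the list alone, 8 and 0; limma's camera adjusted p = 2.05e-05; adjusted p = 0.344 with an estimated correlation).

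Here limma called 463 genes, 262 higher with dominant-negative Ras and 201 lower, and camera 9 lists, 0 with an estimated correlation. Higher genes made up 56.6% of the calls, and 66.9% of 275 calls under median scaling. Without MEK inhibitor replicate 2 or 3 or dominant-negative Ras replicate 2 the count was 140, 178 and 201, and without dominant-negative Ras replicate 3 it was 720.

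Dominant-negative Ras was also compared with the ERK inhibitor, to see where blocking the top of the cascade differed from blocking its bottom: IFNB1, ATF3 and KLF4 were lower, and KLF2, ID1 and ID2 higher. Here too, the level of the block cannot be told apart from the vector, the compound, the solvent or the treatment time. KLF2 was higher by 2.12 ± 0.16 (limma adjusted p = 8e-07), ID1 by 2.09 ± 0.23 (4.73e-05) and ID2 by 2.05 ± 0.35 (0.00149). IFNB1 differed by −2.53 ± 0.17 (limma adjusted p = 3.65e-07), CXCL10 by −2.56 ± 0.24 and the hair keratin gene KRT34 by −3.20 ± 0.50. Without dominant-negative Ras replicate 1 or 3 KRT34 differed by −3.89 and −2.39. ACTA1 was at least 5.33-fold lower (limma adjusted p = 7.96e-09) and the contractile genes TAGLN and CALD1 differed by −1.45 ± 0.17 and −0.96 ± 0.13. Interferon response genes had a median of −0.71, with 23 of 34 lower and 0 higher (adjusted over the list alone, 25 and 0; limma's camera adjusted p = 2.31e-16; adjusted p = 0.182 with an estimated correlation). ATF4 and unfolded protein response genes had a median of −0.44, with 11 of 26 lower and 0 higher (adjusted over the list alone, 14 and 0; limma's camera adjusted p = 5.13e-08; adjusted p = 0.203 with an estimated correlation). ATF3 differed by −0.88 ± 0.12 and HSPA5, an endoplasmic reticulum chaperone, by −0.74 ± 0.11. Squamous genes had a median of −0.58, with 8 of 20 lower and 0 higher (adjusted over the list alone, 11 and 0; limma's camera adjusted p = 5.13e-08; adjusted p = 0.203 with an estimated correlation), with KLF4 at −1.20 ± 0.17 and KRT16 at −1.52 ± 0.20. Matrix protease genes had a median of −0.78, with 9 of 13 lower and 0 higher (adjusted over the list alone, 10 and 0; limma's camera adjusted p = 1.06e-06; adjusted p = 0.203 with an estimated correlation). For NF-kB and cytokine genes the median was −0.50, with 7 of 20 lower and 0 higher (adjusted over the list alone, 11 and 0; limma's camera adjusted p = 1.06e-06; adjusted p = 0.238 with an estimated correlation). SPRY2 was lower by a log2 change of −0.97 ± 0.13.

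This last comparison gave 1145 genes called by limma, 504 higher with dominant-negative Ras and 641 lower, and 11 lists called by camera, 0 with an estimated correlation. Higher genes made up 44.0% of the calls and 4.42% under median scaling. Without ERK inhibitor replicate 1, 2 or 3 the count was 724, 728 and 634, and without dominant-negative Ras replicate 3 it was 709.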

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

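The tests of loss of ERK output, of leukocyte RNA and of a uniformly weaker block by the ERK inhibitor were chosen after the result was seen, and the other tests in this part before.

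Interferon response genes differed between the inhibitors by direct test, with a median of −0.87 for the MEK against the ERK inhibitor, where IFNB1, CXCL10 and OAS2 were each lower. Loss of ERK output as the cause was argued against, since the MEK inhibitor, which lowered the score genes further, left the interferon list at a median of −0.23. A single odd array was argued against by the lowest ERK inhibitor array, whose interferon median was 0.67. Leukocyte RNA in those arrays was argued against as well, with 4 leukocyte genes detected on all 3 of them and 4 in control; of these CSF1R, named after its values were seen, rose by 0.97, but also by 1.05 with the MEK inhibitor and 1.33 with dominant-negative Ras. What may remain is an effect of this compound or dose, or of blocking ERK itself while MEK stays active, and neither was tested.

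Dominant-negative Ras replicate 3 was far from replicates 1 and 2, with 85 genes apart, 53 higher and 32 lower, among them IGFBP5 (4.43 higher), GSTM1 (2.79 higher), SAA1 (−3.00) and SERPINA3 (−2.84), named after their values were seen. An exchange with a MEK inhibitor array was argued against, since over 720 genes its median position between the other dominant-negative arrays (0) and the MEK inhibitor (1) was 0.533 (confidence bounds 0.482 to 0.590). These bounds come from resampling genes of 1 array and do not measure the spread between arrays. Held-out MEK inhibitor arrays lay at 0.738, 0.999 and 0.980, and replicates 1 and 2, held out with replicate 3 among the reference arrays, at 0.423 and −0.050. Dominant-negative Ras replicate 3 thus lay below all held-out MEK inhibitor arrays. The lowest of those, at 0.738, also fell short of the position set beforehand for an exchange, so the argument is limited. Mixture with MEK inhibitor RNA as the whole cause was argued against by 34 of the 85 genes, or 40%, which lay at least 0.5 outside the range of replicates 1 and 2 and the MEK inhibitor arrays. A dim array could not be told apart: 74.1% of the 85 genes were detected on all 12 arrays, against 88.4% of all genes, and its median intensity was the lowest of its group (83.1), but it had the most detected probes of the group (17924), and MEK inhibitor replicate 1, dimmer still (82.9), had 8 genes apart; the labels give no other difference between these replicates, so no biological explanation was tested.

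Score genes differed between the inhibitors, with a median of −1.22 for the MEK against the ERK inhibitor, or −0.57 with 4 members at their bounds. Each pathway gene's ERK inhibitor change divided by its MEK inhibitor change was 1.01 for EGR1, 0.239 for CCND1, 0.199 for EPHA2 and 0.124 for SPRY2, all detected on all 12 arrays. The common ratio of 18 genes was 0.547, with 12 over 2 SE from it, but genes near background enter both values. These were the genes of the score and feedback lists that fell with the MEK inhibitor (limma adjusted p under 0.05). Because the MEK inhibitor change chose them, the choice itself can lower the ratios. Of the 10 genes detected on all 12 arrays, 8 lay over 2 SE from their ratio of 0.487, so no single ratio held for them. Detection does not take a gene off the floor, however. EGR1, furthest from the ratio of the 18 genes (−10.95 SE), fell close to the lowest detected values with both inhibitors. An intensity floor acts on both inhibitors alike, so alone it would leave equal changes. Among the genes detected on all 12 arrays, CCND1, DUSP5, EPHA2, IER5, PHLDA1, PLAUR, SPRED1 and SPRY2 differed directly (limma adjusted p = 4.01e-07 to 0.00166). EGR1 and MYC did not (0.934 and 0.61). For the genes that differed, this argues against a floor alone. A floor together with a uniformly weaker block by the ERK inhibitor could not be excluded by these ratios. A weaker block to which genes differ in sensitivity, output of MEK that does not pass through ERK, or unequal recovery over the 4 days may also remain. These last explanations were not tested.

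Probes without a gene symbol, which no comparison above used, also carried signal. Of 3214 such probes, 150 were higher with the MEK inhibitor, 125 with the ERK inhibitor and 97 with dominant-negative Ras, among 330, 280 and 254 changed.

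Other splits of the arrays were counted for each result. With 3 against 3 there are 10 splits, too few for a share under 0.05. The real split ranked 1 for every gene count: 1682, 1201, 1291, 1076 and 1145 genes for the MEK inhibitor, the ERK inhibitor, dominant-negative Ras, the MEK against the ERK inhibitor and dominant-negative Ras against the ERK inhibitor, with at most 0 in any other split, and 463 for dominant-negative Ras against the MEK inhibitor, with at most 35. List counts were 13, 11 and 9 for the MEK inhibitor, the ERK inhibitor and dominant-negative Ras, against at most 7, 8 and 9 in other splits, and for dominant-negative Ras 2 splits reached that count. Among 100 regroupings of all 12 arrays, the real one included, the real one gave the highest F-test count (2684, highest other 1416). It also gave the most genes changed the same way in all 3 groups (348, highest other 216). Both ranks argue against an absence of any difference between the groups. They do not test how much of the 348 comes from the shared control arrays, since regrouping breaks all group differences at once.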

How the results depend on the processing

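All alternatives in this part were set before the data were examined. Of the named genes' calls under settings that kept every array, 4451 were the same, 128 fell short of the threshold, 48 newly passed and 0 reversed; of the named lists, 819 were the same, 104 fell short and 7 reversed. Leaving out 1 array at a time gave 4065, 263, 16 and 0 for genes, and 822 the same, 41 short and 1 reversed for lists. Median scaling called 747 genes for the ERK inhibitor, 718 for dominant-negative Ras, 275 for dominant-negative Ras against the MEK inhibitor and 152 changed the same way in all 3 groups. It reversed the raw medians of G2/M (−0.025) and cytoskeleton genes (−0.015) with the MEK inhibitor, of G2/M (−0.078) and oxidative phosphorylation genes (−0.033) for the MEK against the ERK inhibitor, and of TGF-beta (−0.022) and oxidative phosphorylation genes (−0.082) for dominant-negative Ras against the ERK inhibitor, through the shift of all genes it leaves in. Relative to the medians of all genes in these comparisons (−0.12, −0.24 and −0.23) none of them reversed. With no filter on detection, dominant-negative Ras against the MEK inhibitor gave 295 genes, and the mesenchymal list with the ERK inhibitor reversed to −0.026. Array weights gave 1996 genes for the ERK inhibitor and 784 for dominant-negative Ras against the MEK inhibitor. For median scaling's counts, the detection filter and the weights the cause was not tested. With a correlation estimated for each list, camera called 2, 0, 1, 2, 0 and 0 lists in the 6 comparisons in report order, and the ERK inhibitor's score median of −1.37 no longer passed (adjusted p = 0.0549). Fits of only the 2 groups compared, with fewer arrays behind the variance, called 791 genes for dominant-negative Ras, 147 against the MEK inhibitor and 495 against the ERK inhibitor. An adjusted p under 0.01 left 883, 472, 569, 481, 138 and 383 genes, and a change of at least 2-fold 329, 190, 201, 228, 90 and 167, by construction fewer. Leaving out 1 array at a time gave 1035 to 2023, 634 to 1547, 745 to 1510, 575 to 1421, 140 to 720 and 634 to 1459 genes, 173 to 386 changed the same way in all 3 groups, and BCL2 family medians of −0.17 to 0.013 for the MEK against the ERK inhibitor, reversed without MEK inhibitor replicate 1. Every one of these fits has 1 array fewer, the higher counts included: 2023, 1547, 1421 and 720 came without dominant-negative Ras replicate 3. What sets the lower counts was not tested. Score medians ranged from −1.98 to −1.82, −1.45 to −1.29 and −1.35 to −1.19 with the 3 treatments.

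Replicate numbers were not taken to pair the arrays in the tests, although the naming rule used the signs of same-numbered differences. The labels name 3 experiments but do not say that a number marks one, and 9 of 18 same-numbered pairs correlated over 0.1 (range −0.19 to 0.33, across genes). As a hint of shared experiments, 15 of the 18 lay above 0. Among them were all 9 between control, MEK and ERK inhibitor arrays. The correlations used each array's deviations from its group mean, so values above 0 for same numbers draw those for different numbers below 0. The median of −0.059 for different numbers therefore adds no contrast. By a strict count, 3 of 12 arrays were closest to their own number in every other group at once. The number as a block gave 1809, 1286, 1420, 1157, 546 and 1250 genes. Of the named results 6 no longer passed with it: G1 cyclins and CDKs with the MEK inhibitor (limma adjusted p = 0.0585), the BCL2 family (0.052) and CCNB2 (0.0505) for the MEK against the ERK inhibitor, basal airway genes for dominant-negative Ras against the MEK inhibitor (0.076), and EPHA2 (0.0523) and SDHA (0.0592) against the ERK inhibitor. DLGAP5 (0.0475, MEK against ERK inhibitor) and ITGA2 (0.0173, dominant-negative Ras against the MEK inhibitor) newly passed. The number as a random effect gave a correlation of 0.0168. No slide is given, so a slide block was not run. Over probes detected on all 12 arrays the score list had fewer than 5 genes and no value, and the random effect and the fit of each probe on its own gave no list values. Signal over background limited genes detected on no array of a group, whose changes are lower bounds, and genes detected on only some, whose changes rest on values near background.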

Other observations

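The families here, and the SRF/MRTF and retinoid tests, were chosen after the result was seen, and both test lists were trimmed of members of the fixed lists after a first run. Of 13 measured collagen genes, 6 were higher with the MEK inhibitor, 10 with the ERK inhibitor and 6 with dominant-negative Ras (2 there under median scaling), with 0, 0 and 1 lower (1 with the MEK inhibitor under loess scaling) and medians of 0.43, 0.71 and 0.43. COL7A1, the anchoring fibril collagen, rose by 0.98, 1.84 and 0.61 in that order, COL18A1 by 0.91, 0.73 and 0.89 and COL4A5, of basement membranes, by 0.95, 0.84 and 0.65. Keratin genes went both ways: 1 of 13 higher and 4 lower with the MEK inhibitor, 5 and 1 with the ERK inhibitor and 3 and 4 with dominant-negative Ras (1 and 5, 4 and 0, and 1 and 4 under median scaling). Among fibroblast markers COL1A1 rose by 0.68, 0.80 and 0.47 (the last not called under median scaling, limma adjusted p = 0.235), and LUM, a matrix proteoglycan named after its value was seen, by 1.33 with the MEK inhibitor. MFAP5, also on the fibroblast list, rose by 4.24, 1.79 and 1.84. FBLN1, the remaining measured gene of that list, was called with no treatment (−0.07, 0.18 and −0.11). KRT18, of simple epithelia, changed by −0.97 with the MEK inhibitor, −0.60 with the ERK inhibitor and −1.02 with dominant-negative Ras.

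Of 5 kallikrein genes 4 fell with the MEK inhibitor, 2 with the ERK inhibitor and 4 with dominant-negative Ras, and 0 rose in any (1 rose with the ERK inhibitor under median and loess scaling). KLK6 changed by −1.07, −0.65 and −1.40. Of 10 serpin genes 4, 0 and 3 fell and 0, 1 and 0 rose (7, 0 and 3, and 0, 2 and 0, under median scaling). SERPINA1, which inhibits neutrophil elastase, changed by −2.32 with the MEK inhibitor and −1.69 with dominant-negative Ras. Of 12 S100 genes 4 fell with the MEK inhibitor and 0 changed with the other treatments (1 fell with dominant-negative Ras under median scaling).

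Muscle-type actin genes ACTA1 and ACTG2, not detected in control, were higher with both inhibitors: ACTA1 at least 3.64-fold and 5.11-fold, and ACTG2 at least 3.23-fold (limma adjusted p = 0.000695) and 4.12-fold (0.000294) with the MEK and the ERK inhibitor. Higher activity of SRF and MRTF, which drive actin genes, may be behind this, but the test did not decide: the lower of the median changes of 14 target genes was 0.13 (camera p in limma 0.0573 with the MEK and 0.0134 with the ERK inhibitor; 0.078 and 0.0303 with an estimated correlation), and 0.12 relative to all genes under median scaling. Over all 23 genes of the untrimmed list the camera p in limma was 0.0492 and 0.000487 (0.23 and 0.05 with an estimated correlation), but that list puts back genes of the fixed lists. ACTA2, another target, changed by −0.59 with the MEK inhibitor.

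Retinoid enzyme genes seen among those higher with the MEK than with the ERK inhibitor raised the question of wider retinoid metabolism. The 12 genes of that list had a median difference of −0.040, with 2 higher and 2 lower, which decides nothing.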
